A study of Homo sapiens with 12 samples.

How the data were processed

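Polyadenylated RNA of 12 libraries of the 697 line, 3 for each of 4 lentiviral vectors, had been sequenced. Per the labels, transduced cells were sorted for EGFP, RNA was purified with a Qiagen RNeasy mini kit and libraries were made by a standard Illumina protocol. The deposited count table holds raw read counts for 57281 Ensembl gene IDs, and 5 further rows hold reads given to no gene. The submitters' processing notes name STAR 2.6, DESeq and the build hg19. The counting program, its strand setting and the annotation release are not given in the sources used here. A second deposited table holds variance-stabilised values on a log2 scale made by the authors from the same libraries. Each of its columns was checked to be an exact function of the same-numbered count column. Gene symbols were taken from the deposited tables, and biotypes, lengths and GC content came from GENCODE by gene ID alone (18878 of the tested genes matched a biotype). That annotation is on another genome build, so no coordinates are given.

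Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, which left 19721. Libraries were scaled by TMM, and a model with 1 mean per group was fitted to all 12 with glmQLFit (robust). Each comparison was tested by the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F. CPM values use TMM-scaled library sizes. Gene totals were 34642709 to 54333433 counts. Reads outside annotated genes made up 11.2% to 23.8% of all reads, ambiguous reads 1.43% to 1.84% and reads without a unique position 7.42% to 11.8%. Where a group held 1 to 3 counts of a named gene, the ratio of summed counts is given with an exact Poisson 95% interval, which covers counting error only.

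Fixed lists of genes, 32 in all, were written before the data were examined, as were the comparisons, the tests, the naming rule and all alternatives except those named as later in the closing parts. Lists with at least 5 tested genes (31) were compared with the other genes by camera at a preset correlation of 0.01, again with an estimated correlation, and tested for a common direction by fry. Adjustment was over the lists of a comparison. Members passing over all genes and adjusted over the list alone were counted. The naming rule took the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM over all libraries and groups that do not overlap. It left out the targeted genes, unnamed genes and pseudogenes. It added up to 3 called members of each list with the smallest p, and 15 genes fixed by name. For shared calls it took the 5 rises and 5 falls with the largest smaller change.

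The steps were tested on simulated data drawn from the means, dispersions and library sizes of these libraries, with 100 genes changed by 4-fold and 100 by 2-fold. For FOXO3 against control (19331 genes run), 71 of the 4-fold and 17 of the 2-fold changes were recovered. For PRDM1 alpha against control (19296 genes) these were 69 and 13, for PRDM1 beta against control (19316 genes) 68 and 12, and for PRDM1 alpha against PRDM1 beta (19284 genes) 72 and 16. Between 2 and 8 unchanged genes were called in each. The G2/M list raised 1.5-fold (19721 genes) was called by camera in all 4, also with an estimated correlation. At the preset correlation 0 of 30 other lists were called. Genes were drawn independently there, while the estimated correlation within the G2/M list was 0.49 in the real libraries. The run therefore cannot show how often camera calls or misses a list of correlated genes. Among single genes, 2-fold changes were mostly missed at this depth and spread.

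Alternatives were RLE scaling, the DESeq2 1.42.0 Wald test, limma on the deposited transformed values, no filter, a filter of at least 1 CPM in at least 3 libraries, a fit to only the groups compared, a test against a fold change of 1.5, the replicate number as a block, and each library left out in turn. Overlaps with a shared control were set beside 40 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.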

Results

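Messenger RNA was sequenced from 12 libraries of the line 697, an established human pre-B acute lymphoblastic leukaemia line that carries the TCF3::PBX1 fusion. The cells carried an empty control vector or a vector with FOXO3, PRDM1 alpha or PRDM1 beta cDNA, with 3 libraries in each of the 4 groups. Gene totals ran from 34642709 to 54333433 counts per library. They were lower in the control vector (36184631 to 43254740) than in PRDM1 alpha (49844168 to 53866978) and PRDM1 beta (50116383 to 54333433), while FOXO3 spanned both (34642709 to 51908828). The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical in part.

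Forced expression was visible at both targeted genes. FOXO3 (ENSG00000118689) had 21.9 ± 4.18 counts scaled to library size (CPM; mean ± SD, n = 3) in the control vector and 631 ± 158 in the FOXO3 group, a log2 fold change of 4.85 (SE 0.27, edgeR adjusted p = 1.25e-06). PRDM1 (ENSG00000057657) had 3.01 ± 0.549 CPM in the control vector, 431 ± 82.1 in PRDM1 alpha and 1126 ± 160 in PRDM1 beta. These were log2 fold changes of 7.16 (SE 0.28, adjusted p = 1.67e-08) and 8.55 (SE 0.30, adjusted p = 3.37e-09). Neither gene passed in the other construct's cells: PRDM1 had a log2 fold change of 0.69 in FOXO3 cells (adjusted p = 0.207), and FOXO3 had 0.30 in PRDM1 alpha (adjusted p = 0.547) and 0.55 in PRDM1 beta (adjusted p = 0.353). The lowest FOXO3 library stood at 492 CPM of FOXO3 and the lowest library of either PRDM1 form at 347 CPM of PRDM1. Gene counts add the transcript of the construct to that of the cell's own locus, and they do not tell PRDM1 alpha from PRDM1 beta, so which form a library carries rests on its label. FOXO3B, a near-identical copy of FOXO3, went from 3.24 to 9.88 CPM in FOXO3 cells (log2 fold change 1.60, adjusted p = 0.0161), a value that stays uncertain because reads can be shared between the copies. The FOXO3B call ended without control replicate 2, control replicate 3 or FOXO3 replicate 1, with adjusted p up to 0.0933.

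**Figure D1:**
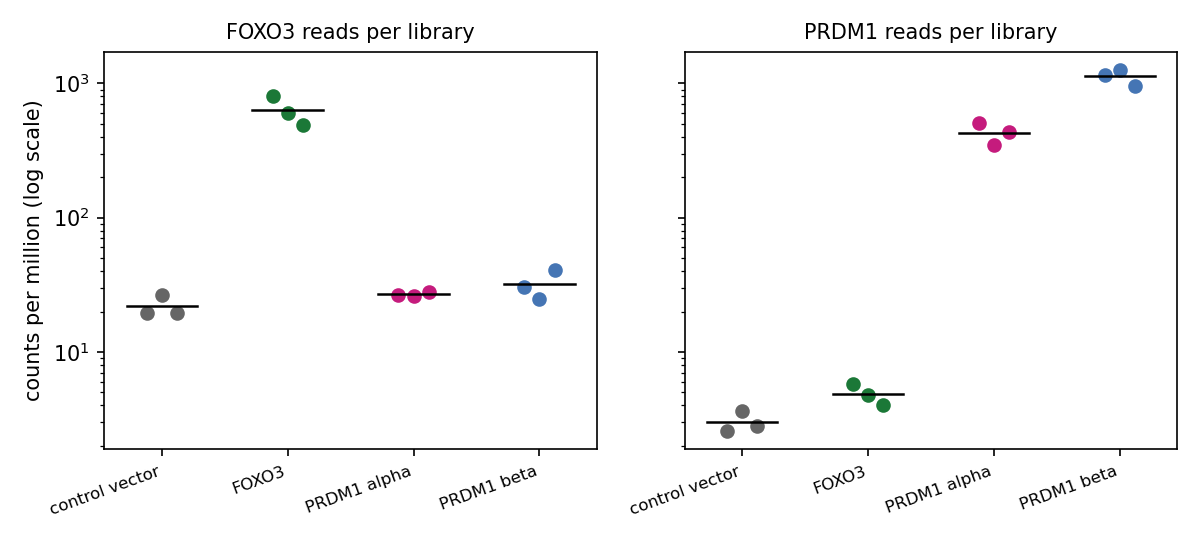
CPM (log axis) of FOXO3 and PRDM1 in each of the 12 libraries, by group, with the group mean as a line. FOXO3 libraries sit between 492 and 803 CPM for FOXO3, and all 6 PRDM1 libraries lie above 347 CPM for PRDM1.

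What FOXO3 does to the transcriptome of these cells was read against the control vector. The selenium carrier SELENOP rose from 0.400 to 15.8 CPM (log2 fold change 5.26, SE 0.50, adjusted p = 2.08e-04), and WDR66 rose from 1.05 to 34.6 CPM (5.03, SE 0.34, adjusted p = 9.73e-06). ITIH3 rose by 3.46, the spectrin gene SPTA1 by 3.19, MYOM1 by 2.97 and the amino acid transporter SLC43A2 by 2.95 on the log2 scale, with adjusted p between 1.77e-04 and 0.00684. The largest falls under the naming rule were smaller: LINC01108 -1.82, SCG2 -1.80, ACSM3 -1.54, the galectin LGALS1 -1.54, GNAZ -1.25 and ERMP1 -1.24, with adjusted p between 0.00681 and 0.0420. Among genes of the fixed lists, the stress regulator SESN3 rose by 1.83, L-selectin (SELL) by 1.86, the B-lineage factors SPIB by 2.36 and TCF4 by 1.30, the receptor MERTK by 1.56, the apoptosis gene BMF by 2.21 and EPSTI1 by 1.73. HLA-DOA rose by 1.37 (adjusted p = 0.00771), and the replication genes ORC1 (-0.79) and POLE2 (-0.83) fell. In total 215 genes changed, 194 higher and 21 lower, of 19721 tested, and 2448 had an unadjusted p under 0.05. The groups of all 215 did not overlap, so that in each case all 3 FOXO3 libraries lay on one side of all 3 controls, which 4345 of the tested genes did where chance gives 10%. Called genes were picked on these same libraries, so their separation, here and in the comparisons below, gives the calls no further support. The count was 78 without control replicate 1, 68 without control replicate 3, 73 without FOXO3 replicate 1 and 108 without FOXO3 replicate 3. Lower genes numbered 1, 3 and 4 without FOXO3 replicates 1, 2 and 3, and 8, 9 and 8 without control replicates 1, 2 and 3. Of the 24 called genes among those named by rule, 10 passed whichever library was left out: SELENOP, WDR66, ITIH3, SPTA1, MYOM1, SLC43A2, SESN3, SELL, SPIB and FOXO3. The calls of LINC01108, ORC1 and POLE2 ended whichever of the 6 libraries was left out. ACSM3, LGALS1, ERMP1 and EPSTI1 passed in 1 of 6 omissions, SCG2 and BMF in 2, TCF4 and FOXO3B in 3, MERTK in 4, and HLA-DOA and GNAZ in 5. The adjusted p of these 14 reached up to 0.166 without control replicate 1, 0.160 without control replicate 2, 0.187 without control replicate 3, 0.182 without FOXO3 replicate 1, 0.146 without FOXO3 replicate 2 and 0.224 without FOXO3 replicate 3.

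Among known FOXO activation targets, SESN3 and SELL rose. They were 2 of 38 measured, and none fell; 7 rose adjusted over the list alone. In 2 alternatives chosen after the data were seen, 7 of 38 rose over all genes without the 3 libraries that stand apart, control replicate 2, PRDM1 alpha replicate 2 and PRDM1 beta replicate 3 (PIK3IP1, KLF2, CCNG2, SESN3, BCL2L11, IRS2 and SELL), and 6 with a stress score as a covariate. No cutoff set in advance picked those 3 libraries. The camera set test placed the list above other genes (adjusted p = 0.0176; adjusted p = 0.818 with an estimated correlation). MHC class II leaned the same way, with 1 of 13 measured up (HLA-DOA) and 2 adjusted over the list alone (camera adjusted p = 0.00795; adjusted p = 0.867 with an estimated correlation). In the same 2 alternatives 5 of 13 rose (HLA-DQB1, HLA-DQA1, HLA-DOA, HLA-DMA and HLA-DMB) and 4 of 13. B cell identity genes had 2 of 28 measured up (SPIB and TCF4) and 3 adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.406 with an estimated correlation). Genes tied to TCF3::PBX1 had 1 of 8 measured up (MERTK) and 3 adjusted over the list alone (camera adjusted p = 0.00322; adjusted p = 0.406 with an estimated correlation). The fry rotation test also gave a common upward direction to B cell identity (adjusted p = 0.00436) and TCF3::PBX1 genes (adjusted p = 0.0122). It passed for no other list that camera called in this comparison (fry adjusted p = 0.341 for FOXO targets, 0.421 for MHC class II and at least 0.299 for each). Cell cycle genes leaned down: in S phase 2 of 29 measured fell and 4 adjusted over the list alone (camera adjusted p = 5.79e-06; adjusted p = 0.818 with an estimated correlation), while in G2/M 0 of 31 passed under either adjustment although the list's median log2 fold change was -0.33 (camera adjusted p = 1.53e-07; adjusted p = 0.818 with an estimated correlation). Of 22 glycolysis genes 0 passed and 6 fell adjusted over the list alone, with a median of -0.73 (camera adjusted p = 5.71e-06; adjusted p = 0.801 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 80 called (camera adjusted p = 1.53e-07; adjusted p = 0.881 with an estimated correlation). The ATF4 amino acid response had 0 of 21 called and 1 lower adjusted over the list alone (camera adjusted p = 7.77e-04, and 0.818 with an estimated correlation). The histone list, which holds replication-dependent histones, had 0 of 66 called (camera adjusted p = 0.00261, and 0.900 with an estimated correlation). No camera call of this comparison held with an estimated correlation. Without control replicate 1 the preset call ended for FOXO targets (adjusted p = 0.267), B cell identity (0.0645) and MHC class II (0.0645). It also ended for FOXO targets without FOXO3 replicate 1 (adjusted p = 0.0734), for MHC class II without FOXO3 replicate 3 (0.0786) and for histones without control replicate 2 (0.115). The glycolysis call held, but its list mean moved from -0.71 to -0.31 without control replicate 2, and its median was -0.45 without the 3 libraries that stand apart. The S phase mean moved from -0.35 to -0.23 without control replicate 1 and to -0.22 without FOXO3 replicate 3. BMF was 1 of 16 BCL2 family genes called and EPSTI1 was 1 of 37 interferon genes called.

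Several genes fixed in advance did not pass in FOXO3 cells. PAX5 had a log2 fold change of 0.50 (adjusted p = 0.524), BCL2L11 0.77 (adjusted p = 0.358), MYC -1.17 (adjusted p = 0.132) and BCL6 -0.95 (adjusted p = 0.272). CDKN1B had 0.36 (adjusted p = 0.694), CCND3 -0.49 (adjusted p = 0.339), TXNIP -0.64 (adjusted p = 0.544), CIITA 0.27 (adjusted p = 0.803), XBP1 0.17 (adjusted p = 0.873) and IRF4 -0.17 (adjusted p = 0.934). Under the alternatives MYC passed in 3 of 17 (adjusted p from 0.0144 to 0.419), BCL2L11 in 2 of 17 (0.0380 to 0.667), PRDM1 in 1 of 18 (0.0315 to 0.559) and the others in none. CCND2 and SDC1 had too few counts in these libraries to be tested.

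PRDM1 alpha is the full-length form. LRRC32 rose from 0.142 to 15.4 CPM (log2 fold change 6.83, SE 1.05, adjusted p = 0.00508), MYO7A from 0.522 to 41.4 CPM (6.29, SE 0.42, adjusted p = 7.57e-06) and GRAMD1C from 0.363 to 23.2 CPM (6.00, SE 0.48, adjusted p = 2.39e-05). FXYD2 rose by 5.23, PLCH2 by 4.46 and the cytolinker PLEC by 4.37 on the log2 scale. The largest falls under the naming rule were LINC01108 -2.22, AFF3 -2.20, SEMA5A -1.77, MYC -1.64 (adjusted p = 0.0192), FAM129C -1.58 and RARRES3 -1.45. MYC went from 312 ± 122 to 99.9 ± 29.4 CPM. From the lists, integrin ITGA6 rose by 2.76 to 119 CPM (adjusted p = 2.97e-04), the T-lineage factors TCF7 and BCL11B by 3.96 and 1.06, the myeloid genes CSF1R and FCER1G by 1.79 and 3.05, MX1 by 5.09, BMF by 2.41, TNFRSF10A by 1.21, LDLR by 1.18 and SLC16A3 by 2.21. BTK (-1.28, adjusted p = 0.00524), HLA-DOA (-1.38, adjusted p = 0.00378) and LTA (-1.49) fell. TRIM63 rose from 2 counts to 85 over 3 libraries each, a ratio of 27.8 with a 95% counting interval of 7.48 to 234. HIST2H4A fell from 31 counts to 3, a ratio of 0.0634 (0.0124 to 0.203), and is uncertain because it has a near-identical copy. In total 428 genes changed, 377 higher and 51 lower, of 19721 tested, and 3145 had an unadjusted p under 0.05. No called gene's groups overlapped, which 20.5% of tested genes showed where chance gives 10%. Lower genes numbered 9, 9 and 74 without PRDM1 alpha replicates 1, 2 and 3, and 19, 14 and 21 without control replicates 1, 2 and 3. The total count was 238 without control replicate 1, 204 without control replicate 3 and 238 without PRDM1 alpha replicate 2. The count was above those of FOXO3 and PRDM1 beta, but not in the 2 alternatives chosen after the data were seen: without the 3 libraries that stand apart it was 371, against 614 in FOXO3 and 415 in PRDM1 beta, and with the stress covariate 627, against 521 and 629. Of the 28 called genes among those named by rule, 18 passed whichever library was left out. The other 10 were LINC01108, AFF3, SEMA5A, MYC, TNFRSF10A, LTA, LDLR, SLC16A3, FCER1G and HIST2H4A. Their adjusted p reached up to 0.145, 0.141 and 0.170 without control replicates 1, 2 and 3, and 0.169, 0.229 and 0.0845 without PRDM1 alpha replicates 1, 2 and 3. MYC missed the threshold without control replicate 1, control replicate 3, PRDM1 alpha replicate 1 or PRDM1 alpha replicate 2, with adjusted p up to 0.123.

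**Figure D2:**
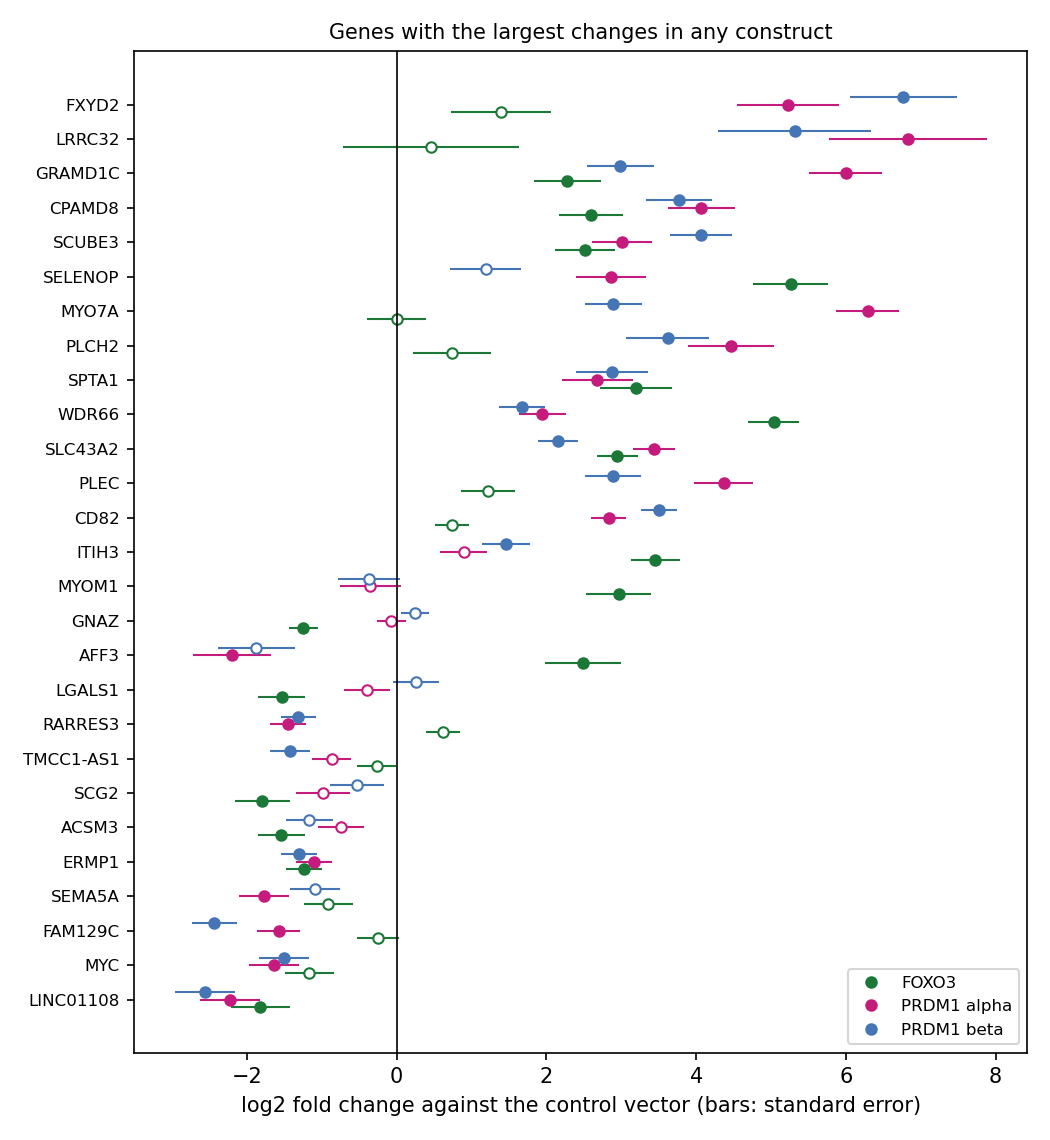
Log2 fold change against the control vector, with its standard error as a bar, of the genes with the largest rises and falls by the naming rule, in FOXO3 (green), PRDM1 alpha (magenta) and PRDM1 beta (blue). Filled points passed an adjusted p of 0.05 and hollow ones did not; LINC01108 fell in all 3 constructs, while AFF3 rose by 2.49 in FOXO3 and had -2.20 in PRDM1 alpha.

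In the MHC class II list, HLA-DOA fell in PRDM1 alpha cells. It was the 1 of 13 measured that passed over all genes, HLA-DOB had a positive log2 fold change (0.30, adjusted p = 0.775), and 9 fell adjusted over the list alone (camera adjusted p = 1.38e-06; adjusted p = 0.804 with an estimated correlation). CD74 had 425 CPM against 871 in the control vector (log2 fold change -1.04, adjusted p = 0.174), HLA-DRA 343 against 815 (-1.25, adjusted p = 0.211) and the transactivator CIITA 63.7 against 90.7 (-0.51, adjusted p = 0.476). Without the 3 libraries that stand apart 1 of 13 passed, and with the stress covariate 5 (HLA-DQA1, HLA-DOA, HLA-DMA, HLA-DPB1 and HLA-DPA1). Medians were nearer 0 without those 3 libraries: -0.68 against -1.03 for MHC class II, -0.40 against -0.85 for ribosomal proteins and -0.45 against -0.84 for glycolysis, where SLC16A3 then did not pass. MHC class I had 0 of 14 called and 2 lower adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.804 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 80 called and 78 lower adjusted over the list alone, with a median of -0.85 (camera adjusted p = 2.42e-28; adjusted p = 0.804 with an estimated correlation). Glycolysis had 1 of 22 measured up (SLC16A3) against a list median of -0.84, and adjusted over the list alone 1 rose and 8 fell (camera adjusted p = 0.00228; adjusted p = 0.836 with an estimated correlation). MYC was the 1 of 32 MYC targets and ribosome biogenesis genes that fell, under either adjustment (camera adjusted p = 0.0272; adjusted p = 0.836 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 called (camera higher, adjusted p = 0.0183; adjusted p = 0.836 with an estimated correlation), and HIST2H4A was the 1 of 66 histone genes that fell (camera adjusted p = 0.0259; adjusted p = 0.836 with an estimated correlation). No camera call of this comparison held with an estimated correlation. The plasma cell program had 1 of 26 measured up (ITGA6) and 2 adjusted over the list alone (camera adjusted p = 0.152). T and NK cell markers had 2 of 10 up (TCF7 and BCL11B), with 3 up and 1 down adjusted over the list alone and 6 of 10 positive. Camera did not pass for them (adjusted p = 0.111; adjusted p = 0.804 with an estimated correlation), while fry gave a common upward direction (adjusted p = 0.0244). Myeloid markers had 2 of 8 up (CSF1R and FCER1G), and the pre-B cell receptor list had 1 of 24 down (BTK), with 1 up and 4 down adjusted over the list alone. TNFRSF10A was 1 of 18 death receptor genes, LTA 1 of 17 NF-kB targets, LDLR 1 of 23 cholesterol genes and TRIM63 1 of 38 FOXO targets called. For the interferon list (MX1, 1 of 37 called) the median was -0.14 and camera pointed down while the mean was 0.11. The MHC class II, MHC class I and ribosomal protein calls held whichever library was left out. By fry none of these 3 lists passed (adjusted p = 0.168, 0.135 and 0.168). Without PRDM1 alpha replicate 2 the call for mitochondrial genes ended (adjusted p = 0.792) and that for MYC targets did (0.189), while the ribosomal mean moved from -0.83 to -0.52. Without control replicate 2 the calls for glycolysis (adjusted p = 0.106, the list mean moving from -0.55 to -0.14), mitochondrial genes (0.106) and histones (0.262) ended. The MYC target call also ended without control replicate 1 (0.224) or control replicate 3 (0.142), mitochondrial genes without control replicate 3 (0.0602) and histones without PRDM1 alpha replicate 1 (0.170).

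**Figure D3:**
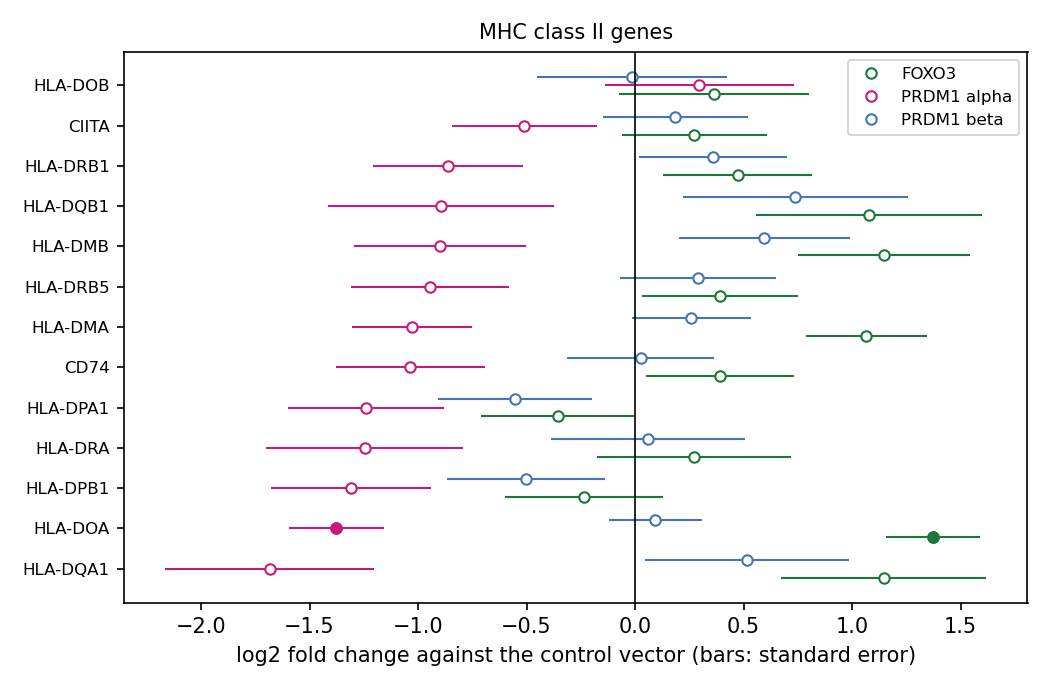
Log2 fold change against the control vector, with its standard error as a bar, of the 13 measured MHC class II genes in FOXO3 (green), PRDM1 alpha (magenta) and PRDM1 beta (blue). Filled points passed an adjusted p of 0.05 (HLA-DOA, 1.37 in FOXO3 and -1.38 in PRDM1 alpha) and hollow points did not.

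PRDM1 alpha left other genes fixed in advance short of the threshold. PAX5 had a log2 fold change of 0.30 (adjusted p = 0.638), BCL6 -0.75 (adjusted p = 0.323), XBP1 0.28 (adjusted p = 0.683), IRF4 -0.76 (adjusted p = 0.485) and TXNIP -1.40 (adjusted p = 0.0967). BCL2L11 had 0.84 (adjusted p = 0.242), CDKN1B -0.31 (adjusted p = 0.655) and CCND3 -0.18 (adjusted p = 0.694). Under the alternatives BCL2L11 passed in 2 of 17 (adjusted p from 0.0136 to 0.483), BCL6 in 1 (0.04996 to 0.566), TXNIP in 1 (0.0177 to 0.302) and the others in none.

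PRDM1 beta, the form that lacks part of the amino terminus, raised many of the same genes. FXYD2 rose from 0.364 to 38.6 CPM (log2 fold change 6.77, SE 0.71, adjusted p = 4.36e-04), LRRC32 by 5.32, SCUBE3 by 4.06, CPAMD8 by 3.77 and PLCH2 by 3.62, and the tetraspanin CD82 rose from 5.24 to 59.4 CPM (3.50, SE 0.24, adjusted p = 1.36e-05). Under the naming rule LINC01108 had the largest fall at -2.56, before FAM129C -2.44 (adjusted p = 8.62e-04), MYC -1.50 (adjusted p = 0.0373), TMCC1-AS1 -1.42, RARRES3 -1.32 and ERMP1 -1.30. TMCC1-AS1 is an antisense gene and stays uncertain, because the strand used in counting is not given in the sources used here. From the lists, ITGA6 rose by 1.72, TCF7 by 3.10, BCL11B by 1.34, CSF1R by 1.86, FCER1G by 3.27, the progenitor factor ERG by 1.53, MX1 by 5.20, EPSTI1 by 1.90, BMF by 2.41 and TNFRSF10A by 1.26, and BTK fell (-1.23). In total 311 genes changed, 287 higher and 24 lower, of 19721 tested, and 2387 had an unadjusted p under 0.05. No called gene's groups overlapped, which 18.2% of tested genes showed where chance gives 10%. The count was 165 without control replicate 1, 126 without control replicate 3 and 188 without PRDM1 beta replicate 1. Lower genes numbered 3, 19 and 36 without PRDM1 beta replicates 1, 2 and 3, and 17, 25 and 8 without control replicates 1, 2 and 3. Of the 24 called genes among those named by rule, 11 passed whichever library was left out: FXYD2, SCUBE3, CPAMD8, PLCH2, CD82, LINC01108, FAM129C, MX1, BCL11B, CSF1R and PRDM1. The other 13, with MYC, LRRC32, TCF7, BTK, BMF and ITGA6 among them, missed the threshold at least once. Their adjusted p reached up to 0.142 without control replicate 1, 0.201 without control replicate 3, and 0.170, 0.0521 and 0.105 without PRDM1 beta replicates 1, 2 and 3. Without control replicate 2 all 24 passed.

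Plasma cell genes leaned upward in PRDM1 beta cells. ITGA6 was the 1 of 26 measured that rose over all genes, and 5 rose adjusted over the list alone (camera adjusted p = 0.00544; adjusted p = 0.763 with an estimated correlation). T and NK cell markers had 2 of 10 up (TCF7 and BCL11B) and 4 adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.714 with an estimated correlation), and fry gave them a common upward direction (adjusted p = 0.00840). MYC was the 1 of 32 MYC targets and ribosome biogenesis genes that fell, under either adjustment (camera adjusted p = 6.12e-05; adjusted p = 0.855 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 80 called, with a median of -0.46 (camera adjusted p = 7.81e-12; adjusted p = 0.933 with an estimated correlation). The unfolded protein response had 0 of 26 called and 1 higher adjusted over the list alone (camera adjusted p = 0.00892; adjusted p = 0.933 with an estimated correlation). Death receptors and caspases had 1 of 18 up (TNFRSF10A; camera adjusted p = 0.0393; adjusted p = 0.855 with an estimated correlation), and S phase had 0 of 29 called (camera lower, adjusted p = 0.0159; adjusted p = 0.996 with an estimated correlation). No camera call of this comparison held with an estimated correlation. MHC class II had 0 of 13 called, also adjusted over the list alone (camera adjusted p = 0.930). Myeloid markers had 2 of 8 up (CSF1R and FCER1G), interferon genes 2 of 37 up (MX1 and EPSTI1), and the pre-B cell receptor list 1 of 24 down (BTK), with 3 up and 2 down adjusted over the list alone. ERG was the 1 of 3 measured stem and progenitor markers that rose, too few for a set test. The calls for plasma cell genes, MYC targets and ribosomal proteins held whichever library was left out, though the MYC target mean moved from -0.39 to -0.25 without PRDM1 beta replicate 3. By fry none of these lists passed (adjusted p = 0.0881, 0.385 and 0.559). Without control replicate 1 the calls for S phase (adjusted p = 0.255), death receptors (0.0874) and T and NK markers (0.0924) ended. Without control replicate 2 those for death receptors (0.0730), the unfolded protein response (0.0947) and T and NK markers (0.0947) did. Without control replicate 3 those for death receptors (0.130) and the unfolded protein response (0.0506) did. Without PRDM1 beta replicate 2 the unfolded protein response (0.0721) and T and NK markers (0.0848) dropped out, and without PRDM1 beta replicate 3 S phase (0.562, with a list mean of 0.02) and death receptors (0.204).

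Among genes fixed in advance, XBP1 stood at 344 CPM against 200 in the control vector (log2 fold change 0.79, adjusted p = 0.289) and BCL2L11 at 197 ± 128 against 80.8 (1.29, adjusted p = 0.0855) in PRDM1 beta cells. PAX5 had 0.20 (adjusted p = 0.827), BCL6 -0.49 (adjusted p = 0.623), IRF4 0.15 (adjusted p = 0.943), CIITA 0.19 (adjusted p = 0.869), CDKN1B 0.26 (adjusted p = 0.781), CCND3 -0.05 (adjusted p = 0.951) and TXNIP -0.66 (adjusted p = 0.538). Under the alternatives BCL2L11 passed in 4 of 17 (adjusted p from 0.00538 to 0.354) and the others in none.

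Set directly against each other, the 2 PRDM1 forms differed in few genes. MYO7A was higher in PRDM1 alpha by 3.40 (41.4 against 3.91 CPM, SE 0.35, adjusted p = 0.00376) and GRAMD1C by 3.01 (23.2 against 2.87 CPM, adjusted p = 0.0224). HLA-DOA was lower in PRDM1 alpha, at -1.47 (12.9 against 35.7 CPM, adjusted p = 0.0283). PRDM1 itself was lower in PRDM1 alpha, at -1.39 (adjusted p = 0.0474), so the dose of the transcript differed between the forms. In all 10 genes differed, 7 higher and 3 lower in PRDM1 alpha, and 841 had an unadjusted p under 0.05. Only 7.98% of tested genes had groups that did not overlap, where chance gives 10%. The count was 4, 1 and 6 without PRDM1 alpha replicates 1, 2 and 3, and 2, 1 and 2 without PRDM1 beta replicates 1, 2 and 3. Of the 4 genes just given, MYO7A alone passed whichever library was left out (adjusted p up to 0.0480). PRDM1 missed the threshold without each of the 6 libraries in turn (up to 0.235), HLA-DOA without each but PRDM1 alpha replicate 3 (up to 0.254), and GRAMD1C without PRDM1 alpha replicate 2, PRDM1 beta replicate 2 or PRDM1 beta replicate 3 (up to 0.154). The other 6, chosen after their values were seen, were LRRTM4 (121 counts in PRDM1 alpha and 1 in PRDM1 beta, a ratio of 115 with a 95% counting interval of 20.2 to 4569), SLC30A2 (log2 fold change 5.48), GRB7 (5.10), SLC34A2 (4.73), STRA6 (4.38) and AC133065.2 (-2.80).

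Of the 13 MHC class II genes measured, HLA-DOA was lower in PRDM1 alpha than in PRDM1 beta over all genes, HLA-DOB had a positive log2 fold change (0.31, adjusted p = 0.963), and 9 were lower adjusted over the list alone, with a median of -1.23 (camera adjusted p = 5.98e-14; adjusted p = 0.370 with an estimated correlation). CD74 had 425 CPM in PRDM1 alpha and 886 in PRDM1 beta (log2 fold change -1.06, adjusted p = 0.953). The camera call for MHC class II held whichever library was left out (adjusted p up to 5.71e-08), while fry did not pass (adjusted p = 0.200). The list mean moved from -1.14 to -0.74 without PRDM1 beta replicate 3, whose MHC class II genes averaged 6.66 log2 CPM against 5.50 and 5.65 in the other PRDM1 beta libraries. Without the 3 libraries that stand apart 0 of 13 passed over all genes and the median was -0.51. B cell identity had 0 of 28 called (camera lower, adjusted p = 0.0251; adjusted p = 0.370 with an estimated correlation), and fry gave it a common lower direction (adjusted p = 0.0486). The B cell identity call ended without PRDM1 alpha replicate 2 (0.194) or PRDM1 beta replicate 2 (0.0591). Another 7 lists had no member called over all genes. FOXO targets had 0 of 38 called (camera lower, adjusted p = 0.00397; adjusted p = 0.679 with an estimated correlation) and death receptors 0 of 18 (camera lower, adjusted p = 0.0251; adjusted p = 0.679 with an estimated correlation). Glycolysis had 0 of 22 called (camera lower, adjusted p = 0.0160; adjusted p = 0.679 with an estimated correlation) and histones 0 of 66 (camera lower, adjusted p = 2.21e-05; adjusted p = 0.679 with an estimated correlation). Mitochondrial genes had 0 of 13 called (camera higher, adjusted p = 8.72e-05; adjusted p = 0.679 with an estimated correlation), ribosomal proteins 0 of 80 (camera lower, adjusted p = 2.03e-15; adjusted p = 0.679 with an estimated correlation) and S phase 0 of 29 (camera higher, adjusted p = 0.0470; adjusted p = 0.725 with an estimated correlation). Without PRDM1 alpha replicate 2 the calls for FOXO targets (0.194), death receptors (0.506), mitochondrial genes (0.780), ribosomal proteins (0.710) and S phase (0.651) ended. Without PRDM1 beta replicate 3 those for FOXO targets (0.540, with a list mean of 0.00), death receptors (0.297) and glycolysis (0.560) ended, and the list means of histones (0.34) and S phase (-0.03) changed sign. Camera then passed for histones in the higher direction (adjusted p = 1.40e-04). S phase also ended without PRDM1 alpha replicate 1 (0.149) or PRDM1 beta replicate 1 (0.0980), death receptors without PRDM1 beta replicate 1 (0.0569) and glycolysis without PRDM1 alpha replicate 3 (0.0778).

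FOXO3 cells were also set directly against each PRDM1 form. Against PRDM1 alpha, 226 genes were higher and 239 lower in FOXO3 cells (465 in all, 2560 at an unadjusted p under 0.05). MYO7A differed by -6.29 (adjusted p = 4.62e-06), LRRC32 by -6.37 (adjusted p = 0.00601), SELL by 2.76 (adjusted p = 2.88e-04), AFF3 by 4.70 (adjusted p = 5.91e-04) and HLA-DOA by 2.75 (adjusted p = 4.07e-05). Against PRDM1 beta, 155 genes were higher and 164 lower (319 in all, 2054 at an unadjusted p under 0.05). FXYD2 differed by -5.38 (adjusted p = 0.00116), CD82 by -2.76 (adjusted p = 5.74e-05), SELENOP by 4.08 (adjusted p = 5.54e-04), HLA-DOA by 1.28 (adjusted p = 0.00822) and SELL by 2.15 (adjusted p = 0.00186). BMF, which rose in all 3 constructs, differed by -0.20 from either form (adjusted p = 0.877 and 0.917). Without the 3 libraries that stand apart all 3 BMF calls against the control vector ended (log2 fold changes 2.25, 2.39 and 2.24; adjusted p = 0.0647, 0.0937 and 0.0932). Over all alternatives its adjusted p ran from 9.04e-06 to 0.0962 in FOXO3, 3.99e-07 to 0.0937 in PRDM1 alpha and 4.78e-07 to 0.0932 in PRDM1 beta. The groups of 464 of the 465 genes and of all 319 did not overlap, against 3950 and 3448 of the 19721 tested genes and 10% by chance. Against PRDM1 alpha the count was 246, 243 and 256 without FOXO3 replicates 1, 2 and 3 and 261 without PRDM1 alpha replicate 1. Against PRDM1 beta it was 154, 142 and 173 without FOXO3 replicates 1, 2 and 3, and 183 and 193 without PRDM1 beta replicates 1 and 2.

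Many genes changed the same way under both PRDM1 forms. LRRC32, FXYD2, CPAMD8, PLCH2 and LINC01134 rose in both, and LINC01108, FAM129C, MYC, RARRES3 and BTK fell in both. In all 231 genes did, 217 higher and 14 lower, where independent lists of these sizes would share 5.49 and 0.0621 of 19721. FOXO3 and PRDM1 alpha shared 49 genes, 46 higher (SLC43A2, SELENOP, PDGFA, SPTA1 and CPAMD8 among them) and 3 lower (LINC01108, ERMP1 and STC2), against 3.71 and 0.0543 for independent lists. FOXO3 and PRDM1 beta shared 52, 50 higher (SPTA1, PDGFA, CPAMD8, SCUBE3 and GRAMD1C among them) and 2 lower (LINC01108 and ERMP1), against 2.82 and 0.0256. No gene was called in opposite directions in FOXO3 and PRDM1 beta or in the PRDM1 forms, and AFF3 and HLA-DOA were in FOXO3 and PRDM1 alpha. In 40 simulations all 4 groups, controls included, were drawn unchanged from the mean levels of the 3 control libraries. The control libraries' own deviations from those means were not kept. The mean number shared was 0.025 for the PRDM1 forms (at most 1) and 0 for both other pairs. Unchanged groups yield almost no called genes, so these numbers do not show how much of the overlap comes from the shared controls. The correlation of log2 fold changes was 0.818 for the PRDM1 forms against 0.519 simulated, but for FOXO3 it was near the simulated value: 0.538 with PRDM1 alpha against 0.515 (at most 0.532) and 0.540 with PRDM1 beta against 0.513 (at most 0.527). The same sign was found for 76.4% of genes in the PRDM1 forms (67.0% simulated), 69.5% in FOXO3 and PRDM1 alpha (67.0%) and 70.4% in FOXO3 and PRDM1 beta (66.9%). The covariance of log2 fold changes across genes was 0.466 for the PRDM1 forms against 0.0950 simulated, 0.275 for FOXO3 and PRDM1 alpha against 0.0951, and 0.247 for FOXO3 and PRDM1 beta against 0.0947. The 3 control libraries cannot be split with at least 2 on each side, so part of the excess may come from the shared controls. The number shared by the PRDM1 forms was 127 without control replicate 1 and 94 without control replicate 3. For FOXO3 and PRDM1 alpha it was 19 and 17 without control replicates 1 and 3, and 20 and 30 without FOXO3 replicates 1 and 3. For FOXO3 and PRDM1 beta it was 19 and 10 without control replicates 1 and 3, 21 and 30 without FOXO3 replicates 1 and 3, and 31 without PRDM1 beta replicate 1.

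Libraries of 1 group differed among themselves in stress and ribosomal genes. Early stress genes averaged 8.18 log2 CPM in PRDM1 beta replicate 3, against 5.00 and 4.26 in the other PRDM1 beta libraries. Ribosomal protein genes took 3.76% of gene counts in PRDM1 alpha replicate 2, against 8.38% and 10.0% in the other PRDM1 alpha libraries, and mitochondrially encoded genes took 9.18% against 4.34% and 3.56%. Reads outside annotated genes were 23.8% of all reads in that library. None of the 19 stress genes passed in any of the 3 comparisons with the control. In PRDM1 beta the stress list's median was 0.82 and its mean 0.40 while camera pointed down (adjusted p = 0.595). That median was -0.96 without the 3 libraries that stand apart and -1.82 without PRDM1 beta replicate 3, so its sign changed with that library.

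**Figure D4:**
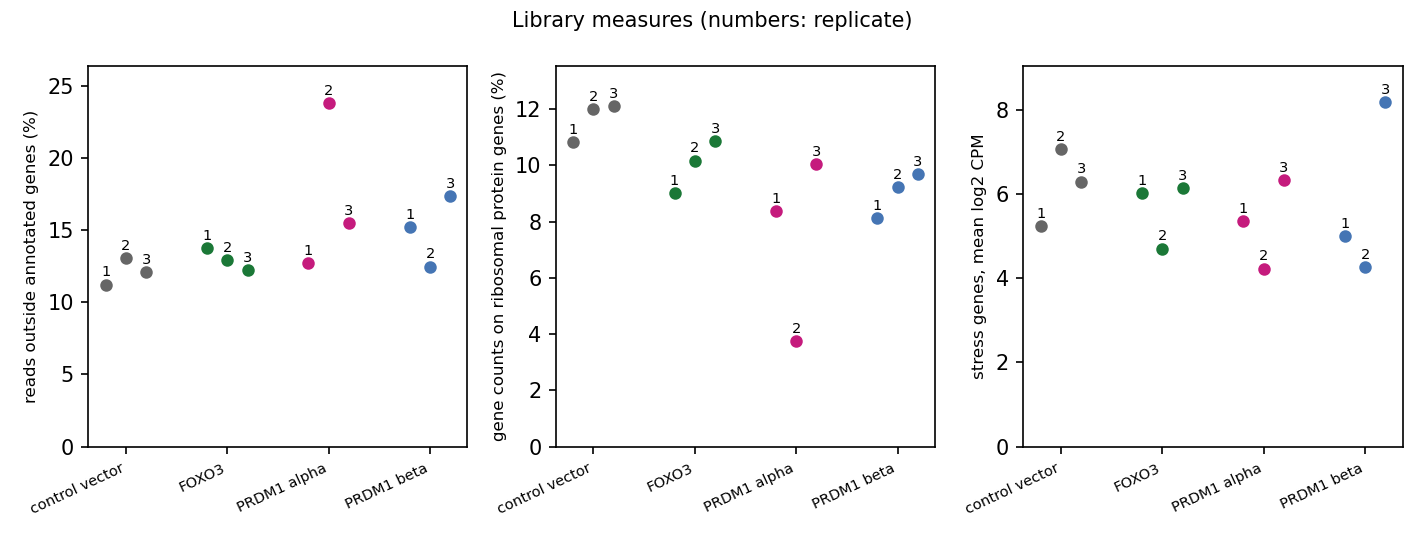
Reads outside annotated genes (% of all reads), gene counts on ribosomal protein genes (%) and mean log2 CPM of early stress genes in each library, by group, with the replicate number at each point. PRDM1 alpha replicate 2 has 23.8% of reads outside genes and 3.76% on ribosomal protein genes, and PRDM1 beta replicate 3 has the highest stress mean at 8.18.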

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

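The tests of GC content with gene length and both tests of a mislabelled library, as well as the spread between libraries set beside the genomic DNA and unspliced RNA tests and the intervals set beside the shares of rises, were chosen after the results were seen, and the other tests before. AFF3 rose in FOXO3 cells and fell in PRDM1 alpha cells, and HLA-DOA did the same. Both stand here because a direct test of FOXO3 against PRDM1 alpha gave a difference, with log2 values of 4.6977 for AFF3 (adjusted p = 5.91e-04) and 2.7513 for HLA-DOA (adjusted p = 4.07e-05). That test uses the same fit as the opposite calls that picked the genes, so it gives them no separate support. The AFF3 fall passed in 10 of 17 alternatives (edgeR, DESeq2 or limma adjusted p up to 0.229) and the HLA-DOA fall in 17 of 17. Reads outside annotated genes, which no comparison uses, exceeded the highest control library (13.056%) in FOXO3 replicate 1 (13.735%), PRDM1 alpha replicate 2 (23.802%), PRDM1 alpha replicate 3 (15.468%), PRDM1 beta replicate 1 (15.189%) and PRDM1 beta replicate 3 (17.361%). Reads that fit more than 1 gene did so in PRDM1 beta replicate 2 (1.837% against 1.8285%).

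More genes rose than fell under every construct. A biological explanation would be genes silent in the control vector that the constructs switch on, but only 64 of 194 rises in FOXO3, 223 of 377 in PRDM1 alpha and 130 of 287 in PRDM1 beta had a control mean below 1 CPM, so it leaves most rises in FOXO3 and PRDM1 beta unexplained. With RLE factors the lowest share of rises over the 3 comparisons was 0.893, with all libraries thinned to the smallest total 0.9013, and with the percentage of reads outside genes as a covariate 0.8. The second value (interval from 0.868) argues against shallower control libraries as the whole cause. Normalization stays undecided because RLE moved almost nothing (median log2 fold changes within 0.01 of 0, as with TMM). With reads outside genes as a covariate the shares in FOXO3, PRDM1 alpha and PRDM1 beta were 0.80, 0.932 and 0.863, all above the bound of 0.75 set before. The interval added later ran from 0.7497 to 0.844 in FOXO3, so these reads stay undecided. FOXO3 libraries had 13.0% of such reads against 12.1% in the control vector, and 90.2% of their called genes rose. The intervals are binomial over called genes taken as independent, and measure no spread between libraries. Among genes with at least 5 CPM in the control vector, which can fall as well as rise, the shares were 0.80 in FOXO3, 0.717 in PRDM1 alpha and 0.84 in PRDM1 beta, so that a floor in the control vector stays undecided.

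Early stress genes in PRDM1 beta replicate 3 lay 2.3638 log2 units above the mean of their group. After smooth trends on length and on log2 GC content were removed the deviation was 2.2851, which argues against those trends. Its SE of 0.253 is taken over the 19 genes of the list in 1 library, so it measures no spread between libraries. PRDM1 and FOXO3 differed by at most 0.5733 log2 units from the other PRDM1 beta libraries, with PRDM1 far above its level in the control vector and FOXO3 groups, but gene counts do not separate the PRDM1 forms or a partial mixture, so a mislabelled or mixed library stays undecided. No biological explanation was tested, since no group of the design stands for stress.

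In PRDM1 alpha replicate 2, which had the most reads outside genes, gene families that are silent in B cells took 1.575 times the share they had in the other 2 PRDM1 alpha libraries (1.47 to 1.68, counting error only). The other 2 libraries differed by 1.52 times between themselves, so genomic DNA stays undecided. Sense intronic genes took 1.9777 times their share, where the other 2 differed by 1.14 times, and ribosomal protein genes 0.406 times theirs. Both go with more unspliced or nuclear RNA. Mitochondrially encoded genes, whose transcripts are not nuclear, took 9.18% of gene counts against 4.34% and 3.56% in the other 2. More nuclear RNA alone would not raise that share, so the cause stays undecided. PRDM1 differed by -0.4385 log2 units from the other 2 libraries, which for the same reason leaves a mislabelled or mixed library undecided. No biological explanation was tested, since the 3 libraries share 1 label.

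In all 6 comparisons the real grouping gave the most genes of all 10 splits of the 6 libraries into 3 and 3, and no other split gave any (highest 0). With 10 splits the share at or above the real value can never be below 0.1, so that 1 of 10 is too few splits for a share under 0.05.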

How the results depend on the processing

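Leaving out the 3 libraries that stand apart (control replicate 2, PRDM1 alpha replicate 2 and PRDM1 beta replicate 3), the stress score as a covariate and thinning were chosen after the data were seen. Counts within 1.5 times the reported one are not repeated, and where not stated the cause was not tested. Counts are in the order FOXO3, PRDM1 alpha and PRDM1 beta against control, PRDM1 alpha against PRDM1 beta, FOXO3 against PRDM1 alpha and against PRDM1 beta, then shared genes of FOXO3 and PRDM1 alpha, FOXO3 and PRDM1 beta, and both forms. DESeq2 gave 618, 803, 644, 63, 860 and 624 genes, and 145, 153 and 411 shared. A tested fold change of 1.5, a stricter question by construction, gave 60, 245, 163, 6, 217 and 156, and 15, 14 and 126. Without a filter the first 4 were 371, 693, 491 and 49, and the first 2 overlaps 98 and 102. With stress as a covariate FOXO3 had 521 and PRDM1 beta 629 against control, the forms differed in 20, FOXO3 differed in 782 and 541, and 115, 149 and 368 were shared. Without the 3 libraries apart FOXO3 had 614, the forms differed in 1, FOXO3 and PRDM1 beta in 534, and the first 2 overlaps were 103 and 125. Only the groups compared gave PRDM1 beta 122 and the forms 5, limma on the deposited matrix gave the forms 21, and the replicate block gave them 6. Of 18 pairs of libraries with the same number in other groups, 7 had a correlation of deviations over 0.1 (-0.55 to 0.54). Of 12 libraries 5 matched their own number best. PRDM1 alpha replicate 1 and PRDM1 beta replicate 1 correlated at 0.9901 in log2 CPM, above the highest value within a group (0.9892). These correlations leave it undecided whether the numbers pair the libraries. The heat shock genes HSPA8, HSPH1, DNAJB1, HSPA1A and HSPA1B, picked after the data were seen, were highest in replicate 3 of each group. HSPH1 had 560, 220, 490 and 469 CPM there in control vector, FOXO3, PRDM1 alpha and PRDM1 beta. For these genes the number thus tracked a shared difference, which the main model without a block ignores. FOS did not follow it, being highest in replicate 2 of the control vector and replicate 1 of FOXO3. Leaving out 1 library gave 68 to 161, 204 to 470, 126 to 324, 1 to 6, 243 to 322 and 142 to 263, and 17 to 53, 10 to 69 and 94 to 236 shared. Fewer samples give less power, but some omissions raised the count, as in PRDM1 alpha without its replicate 3 (470 against 428). The part due to power was not tested. Of 80 called named genes 80 stayed past the threshold with DESeq2, 79 with limma, 77 with RLE, 70 with the block, 66 without the 3 libraries apart and 60 with only the groups compared. No named gene changed direction where called. Of 45 named results not called, 5 passed without the 3 libraries apart, 3 with DESeq2 and 3 with the stress covariate. Of 33 set test calls, RLE and the block kept 33, the stress covariate 29, the stricter filter 27, the fit without the 3 libraries apart 20, fry 4 and an estimated correlation 0. Without the 3 libraries apart the set test's direction reversed for mitochondrial genes in PRDM1 alpha, whose mean stayed above 0 (0.061301), and list means reversed for histones (-0.45268) in PRDM1 beta, and in PRDM1 alpha against PRDM1 beta FOXO targets (0.14462), S phase (-0.13215), death receptors (0.055301), ribosomal proteins (0.096838) and histones (0.26444). Histones also reversed in PRDM1 alpha with the stress covariate (0.078182). Without PRDM1 beta replicate 3 the means reversed for histones in PRDM1 beta (-0.71937, range over the libraries left out -0.71937 to 0.54) and between the forms (0.33885, range -0.92623 to 0.33885), and for S phase between the forms (-0.033443, range -0.033443 to 0.31659). The means of S phase in PRDM1 beta (0.016491) and of FOXO targets between the forms (0.0033409) also crossed 0 there, while the set test's direction stayed. Some reversed lists passed camera in the new direction. Without the 3 libraries apart these were histones in PRDM1 beta (adjusted p = 3.27e-05) and between the forms (0.00195), and ribosomal proteins between the forms (0.00829). Without PRDM1 beta replicate 3 they were histones in PRDM1 beta (camera adjusted p = 1.48e-12) and between the forms (1.40e-04). Genes of low count were recovered less often in the simulations. Over all levels 68% to 72% of 4-fold changes were recovered, and at 5 CPM or more at least 96.2%. Of 2-fold changes at most 30.4% were recovered even at 5 CPM or more, so low counts alone do not account for those missed.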

Other observations

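Several further fixed lists had no member called over all genes with all 12 libraries. V(D)J recombination genes had 0 of 12 called in each construct (median log2 fold change -0.00 in FOXO3, -0.19 in PRDM1 alpha and -0.13 in PRDM1 beta), p53 targets 0 of 22 (0.11, -0.17 and 0.18), autophagy 0 of 17 (0.04, -0.12 and 0.05) and PI3K-AKT-mTOR components 0 of 25 (0.14, 0.14 and 0.07). Cyclins, CDKs and inhibitors of G1 had 0 of 17 called (0.12, -0.05 and 0.04), although their mean in PRDM1 alpha was 0.13 while the median and camera pointed down. Erythroid and megakaryocyte markers had 0 of 5 called, as did epithelial and fibroblast markers. Adjusted over the list alone some members passed: 2 p53 targets, 1 erythroid and 1 epithelial marker were higher in FOXO3, 1 V(D)J gene was lower in PRDM1 alpha, and 1 PI3K-AKT-mTOR component was higher in each construct, with 1 lower in PRDM1 beta. In an alternative chosen after the data were seen, without the 3 libraries that stand apart, PIK3IP1, PIK3CA, IGF1R and IRS2 (4 of 25 PI3K-AKT-mTOR components), TP53INP1 (1 of 22 p53 targets) and CDKN2D (1 of 17 cyclins, CDKs and inhibitors) rose over all genes in FOXO3, and IRS2 and CDKN1C in PRDM1 alpha. For autophagy in FOXO3 cells the mean was -0.10 and camera pointed down against a median above 0. For B cell identity in PRDM1 beta the median was -0.06 and the mean 0.09, with 4 of 28 measured higher adjusted over the list alone. TCF3::PBX1-associated genes in PRDM1 beta had a median of -0.11 and a mean of 0.06.

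Genes near the threshold were CD79B in PRDM1 beta (log2 fold change 1.18, adjusted p = 0.0509), ROR1 in FOXO3 (0.74, adjusted p = 0.0604) and PIK3IP1 in FOXO3 (2.18, adjusted p = 0.0816), chosen after their values were seen. Early stress genes averaged between 4.23 and 8.18 log2 CPM over the 12 libraries, and control replicate 2 lay 0.873 above the mean of its group. Deviations of larger size were -0.968 in control replicate 1, -0.918 in FOXO3 replicate 2, 1.02 in PRDM1 alpha replicate 3 and -1.55 in PRDM1 beta replicate 2. Those libraries were kept when the 3 that stand apart were left out, so this score alone does not set control replicate 2 apart.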
